A study of Mus musculus with 4 samples.

How the data were processed

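RNA was taken from the aorta of apoE-/- control mice of the C57BL/6 strain (B6) and of Ath29 congenic mice, each on chow or Western diet, and hybridised to 4 Affymetrix mouse arrays, 1 per group, per the labels. Mice were weaned at 3 weeks of age and changed diet at 4 weeks, for 2 weeks, and biotin-labelled cRNA was prepared from 8 ug of total RNA, per the labels' protocols. The same protocols name liver as the tissue extracted, while the source label and the series' design text name aorta. The authors deposited 1 table of intensity values on a linear scale, read as such from the values, which run from 0.57 to 13421. The software, background correction and normalization behind these values are not given in the sources used here, so how probes were summarised and whether arrays were scaled to each other before deposit stays unknown. The array medians of 27.9 to 28.8 lie close together. No probe-level files were analysed here.

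Probe sets were named through the platform annotation given with the data, and symbols were updated through gene identifiers to a reference gene table of assembly GRCm38.p6. Of 45101 probe sets, 64 are controls, 34958 have 1 gene symbol, 932 have several and were left unnamed, and 9160 have none. Of those with 1 symbol, 34754 were found in the reference table, which gave chromosomes and gene order only. No coordinates are given because the data file names no genome build.

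The intensities were taken to log2, each array was shifted to a common median (factors 1.02 for B6 chow, 0.992 for B6 Western, 0.990 for Ath29 chow and 0.997 for Ath29 Western), and values below the 25th percentile of all values (9.59) were raised to it. A difference against a value at this floor is a bound. Probe sets with a mean log2 value above the median of all probe sets (4.78, or 27.4 on the linear scale) were kept, 22518 in all, and each gene was read from its probe set with the highest mean, which gave 11718 genes. The 4 differences are Ath29 minus B6 on chow and on Western diet, and Western minus chow in B6 and in Ath29 mice. Genes at least 2-fold different were counted in each direction. The strain differences on the 2 diets use different arrays, as do the diet differences of the 2 strains, so genes different in the same direction in both were counted beside genes different in opposite directions. With 1 array per group there is no replicate and no test of a single difference.

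Gene lists cover cholesterol synthesis, fatty acid and triglyceride synthesis, cholesterol efflux, fatty acid oxidation, oxidative phosphorylation, chemokines and cytokines, adhesion molecules, interferon response, matrix remodelling, antigen presentation, cell cycle, unfolded protein response, oxidative stress, immediate-early, clock, heat shock and ribosomal protein genes. They also cover markers of macrophages, T and NK cells, B cells, neutrophils, smooth muscle, endothelium, fibroblasts, white and brown fat, skeletal and heart muscle, hepatocytes, nerve and red cells, and sex-linked transcripts. The sex-linked list had only 2 measured members, so 31 of the 32 lists were evaluated. Each list's median difference was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. A list was described as shifted where the percentile was under 2.5 or over 97.5 on the same side in both differences of a kind. The percentiles describe these 4 arrays and are no test across mice. Shares of genes on a chromosome carry 95% Wilson intervals.

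Named genes were the 12 highest and 12 lowest by the smaller of the 2 differences for strain and for diet, the 3 highest and 3 lowest of each single difference, the 6 most positive and 6 most negative strain by diet differences, up to 6 members of each list, up to 15 chromosome 9 genes ranked by the smaller strain difference, and Rcn2, Apoe, Xist and Y-linked genes. These rules, the lists, the comparisons and most alternatives were fixed before the data were examined. Acaa1b, Acta2, Ccl2, Ccr2, Clec1b, Clec7a, Cma1, Cpa3, Gp1bb, Hp, Mybpc3, Myh7, Myl2, Pf4, Pln, Saa3, Srebf2, Tinag, Tpsb2, Tubb1 and the genes that bound stretches of chromosome 9 were named after their values were seen. Named genes with a value below 27.4 on at least 1 array, whose differences against it are not exact, were 2900055J20Rik, A530053G22Rik, Aoc1, Aqp7, C920006O11Rik, Cckbr, Cd300lb, Chil3, Ciart, Cma1, Cxcl2, Fam227a, Fastkd3, Fgl1, Gm7694, Hand2, Hhip, Igha, Il1rn, Il6, Jchain, Krtap21-1, Mb, Msmo1, Mybpc3, Myh1, Myh7, Myl7, Myom2, Nap1l3, Nnat, Nr1d1, Nxpe4, Ocln, Plekha7, Plet1os, Rac2, Serpina3n, Tinag, Tnni3, Tpsab1, Trim67, Ttll10, Wnt3a, Zfp772 and Zmat4.

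The alternatives were quantile normalization, no shift, a common 75th percentile, no filter, a filter at the 75th percentile, a floor at the 40th percentile, no floor beyond 1, the mean of all probe sets of a gene, leaving out probe sets that can bind several transcripts, thresholds of 1.5-fold and 3-fold, unmatched random lists, and an additive limma fit of strain and diet with 1 residual degree of freedom and Benjamini-Hochberg adjustment. Leaving out muscle and fat list genes, and leaving out the B6 Western array, were added after the data were seen. For the latter, unchanged groups sharing the B6 chow array were simulated 100 times, with the spread of 1 array drawn from strain by diet differences of genes of similar level. Those strain by diet differences may hold real differences and include the B6 Western array. Independent lists would share 3.76 higher and 1.92 lower genes. The counting rule, the list test and the limma fit were tested on simulated data for the strain difference shared by both diets, with 11718 genes and 200 changed. The 2-fold rule recovered 0 of 50 genes changed 1.5-fold, 17 of 50 changed 2-fold, 49 of 50 changed 4-fold and 50 of 50 changed 8-fold, and called 6 of 11518 unchanged genes. Simulated genes of similar level had the same spread, and 2 unchanged ones differed in opposite directions, against 73 genes in the real arrays. These rates therefore need not hold for the real arrays. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.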

Results

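Gene expression was measured in the aorta of mice from 4 groups, with 1 array per group. B6 mice, the controls, were apoE-/- animals of the C57BL/6 strain, which lack apolipoprotein E and are labelled as having atherosclerosis. Ath29 mice are congenic, which means that they carry a donor segment of another strain on the C57BL/6 background, and they are labelled as resistant to atherosclerosis. The apoE-/- genotype is given here for the controls only, and the values below do not settle whether Ath29 mice share it. Ath29 is an atherosclerosis locus of mouse chromosome 9. Mice of each strain stayed on chow or were moved at 4 weeks of age to a Western diet, rich in fat and cholesterol, for 2 weeks. The 4 arrays carried 45101 probe sets each, with median intensities of 27.9 in B6 chow, 28.7 in B6 Western, 28.8 in Ath29 chow and 28.6 in Ath29 Western. After filtering, 11718 genes were compared. With 1 array per group no difference below has a replicate check, and the only p-values given come from an additive fit of strain and diet. The labels do not say whether an array holds RNA of 1 mouse or of a pool.

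The arrays carried strong signals of vessel wall. Contractile smooth muscle genes, among them Acta2 and Myh11, had a median log2 intensity of 11.21 in B6 chow, 10.80 in B6 Western, 10.43 in Ath29 chow and 10.87 in Ath29 Western. The extract protocol in the labels names liver while the source label says aorta, and albumin (Alb), the most abundant hepatocyte transcript, lay between 33.0 and 64.6 intensity units. Of the 25 listed hepatocyte genes, 5 passed the filter, 15 lay below it and 5 had no probe set of their own. Their median log2 difference was 0.25 and -0.06 between strains on chow and Western diet, and 0.45 and 0.15 between diets in B6 and Ath29 mice. The probe set of Apoe, the knocked-out gene, read 7.03, 19.2, 8.51 and 25.2 in B6 chow, B6 Western, Ath29 chow and Ath29 Western. All 4 values lie below the expression filter of 27.4, but whether the probes fall inside the deleted part is not known here, so this reading does not check the genotype. Xist, the transcript that silences one X chromosome in females, read between 4071 and 4671 on every array. The probe sets of the Y-linked genes Eif2s3y and Uty read at most 24.0 and 21.2 on any array, while the Usp9y probe set read between 125 and 236. Since the Apoe, Eif2s3y and Uty probe sets read up to 25.2, single array values below 27.4 are not told apart from background here, and differences that rest on one are not exact.

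Some signals of other tissue and of RNA integrity differed between the arrays. Heart muscle genes had a median log2 intensity of 8.76 in B6 Western against 5.89 in B6 chow, 5.99 in Ath29 chow and 5.11 in Ath29 Western. Brown fat genes had medians of 9.29 in B6 chow, 10.69 in B6 Western, 10.05 in Ath29 chow and 9.54 in Ath29 Western. White fat genes followed the same order, with 8.40, 10.31, 10.05 and 9.15. The ratio of the 3' to the middle actin probe set was 5.10 in B6 chow, 5.63 in B6 Western, 10.2 in Ath29 chow and 7.62 in Ath29 Western. For Gapdh that ratio ran from 8.87 to 10.6, lowest in Ath29 chow and highest in Ath29 Western. In B6 chow, B6 Western, Ath29 chow and Ath29 Western, the 3' to 5' ratio was 24.4, 25.4, 31.5 and 28.5 for actin. For Gapdh it was 31.3, 29.0, 22.8 and 28.0, so 3' signal far exceeded 5' signal on every array. The bioB hybridisation control read 394 and 418 in the B6 arrays and 516 and 566 in the Ath29 arrays.

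**Figure D1:**
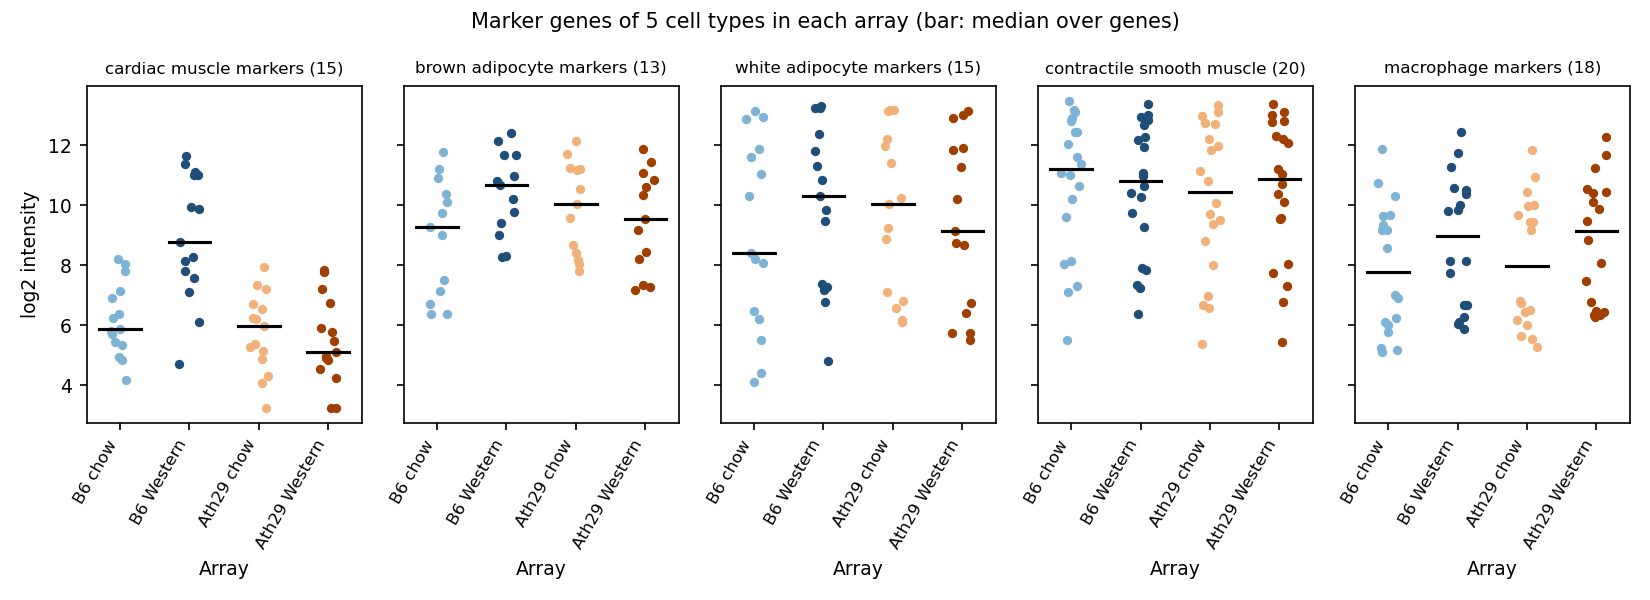
Log2 intensity of each measured marker gene (points) of 5 cell types in the 4 arrays, with the median over genes as a bar. Heart muscle genes stand highest in B6 Western (median 8.76), and both fat lists are lowest in B6 chow and highest in B6 Western.

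The comparison of strains asks which aortic transcripts differ between mice with and without the Ath29 segment, on either diet. Parp3, an ADP-ribosyltransferase of the DNA damage response, read 520 and 526 in Ath29 mice on chow and Western diet against 2655 and 2683 in B6 mice, 5.26-fold and 5.08-fold lower. Nnmt, which methylates nicotinamide, was 5.81-fold and 6.82-fold lower in Ath29 mice. Nxpe4 read 117 and 124 in B6 mice and 14.95 and 12.9 in Ath29 mice, the latter not told apart from background. Fez1, an adaptor of axonal transport, was 8.59-fold lower on chow and 3.76-fold lower on Western diet. Tpsab1, a mast cell tryptase, read 97.8 and 98.0 in Ath29 mice against 17.8 and 19.9 in B6 mice, again in the range of background. Among genes higher in Ath29 mice by at least 2-fold on both diets were also the actin capping gene Tmod3, with log2 differences of 1.62 and 1.35, the phospholipid scramblase Plscr2, with 1.82 and 1.35, and the trafficking gene Trappc4, with 1.34 and 1.56. Some of these depend on the probe set. A pair of other Parp3 probe sets gave -0.21 and -0.09 on chow and 0.21 and -0.18 on Western diet, and without probe sets that can bind several transcripts, the mean strain difference of Tmod3 is -0.80 and that of Trappc4 -0.29.

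At least 2-fold in the same direction on both diets, 9 genes were higher in Ath29 mice and 21 lower, 30 in all. A further 73 genes differed by at least 2-fold in opposite directions on the 2 diets, 67 of them higher in Ath29 mice on chow and lower on Western diet. Independent differences would put 2.14 genes higher and 4.65 lower on both diets. The 30 shared genes exceed that, but not the 73 in opposite directions. At 1.5-fold, independent differences would put 47.5 genes higher and 89.4 lower, against 51 and 97 found. Lower in Ath29 mice on chow and Western diet were Clmp, an adhesion molecule (-1.52 and -1.64), Tipin, a replication fork protein (-1.54 and -1.48), Nicn1 (-1.32 and -1.34), Fastkd3, a mitochondrial RNA-binding protein (-1.47 and -1.35), and C920006O11Rik (-1.63 and -3.28, the latter a bound). The platelet genes Ppbp (-1.39 and -1.60) and Tubb1 (-1.43 and -1.24) were also lower. Higher were Tpbg, the trophoblast glycoprotein (1.13 and 1.27), the vesicle GTPase Rab4a (1.14 and 1.31), the leukocyte GTPase Rac2 (1.05 and 1.27), Zmat4 (1.19 and 1.22) and Ttll10 (1.01 and 3.38). Other probe sets gave -1.67 and 0.17 for Clmp and -0.22 and -0.08 for Nicn1, and a pair for Tpbg gave 0.21 and 0.09 on chow and 0.67 and -0.09 on Western diet. Just under 2-fold on at least 1 diet were Cckbr (0.95 and 1.19), the mitotic kinase Pbk (0.97 and 0.95) and Nnat (1.70 and 0.94). Fastkd3, C920006O11Rik, Rac2, Zmat4, Ttll10, Cckbr and Nnat had a value below 27.4 on at least 1 array, so their differences are not exact. Of the 21 lower genes, 6 belong to the heart or skeletal muscle lists, whose signal was highest in B6 Western: Myh1, Tnni3, Mb, Mybpc3, Pln and Sln. The values of Myh1 (-4.23 and -5.27) and Tnni3 (-1.57 and -5.50) are bounds, since both Ath29 arrays lay at the intensity floor of 9.59. An additive fit with limma, which takes the strain by diet difference as error, called 0 genes at an adjusted p under 0.05, with 304 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0738.

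Of the 30 shared genes, 13 lie on chromosome 9, or 43.3% (95% Wilson interval 27.4 to 60.8), against 5.52% of all genes compared. Among 10000 random sets of 30 genes the median was 1 chromosome 9 gene and the highest 7. Of the 13, 9 were lower in Ath29 mice (Nxpe4, Nnmt, Parp3, Fez1, C920006O11Rik, Clmp, Tipin, Nicn1 and Sln) and 4 higher (Tmod3, Plscr2, Trappc4 and Tpbg). With no filter on low values the share was 18.1%, or 13 of 72 genes, and without the B6 Western array 17.1% of 111 genes, where unchanged groups sharing the B6 chow array gave up to 188 genes and 9.52%. Of the 73 genes that differed in opposite directions, 2 lie there, Acaa1b and Tinag, or 2.74%. Acpp, with -0.97 and -1.01, and the MAP kinase phosphatase Dusp7, with 1.08 and 0.93, lay close to the 2-fold line. At 1.5-fold, 28 of 148 shared genes lie on chromosome 9 (18.9%, interval 13.4 to 26.0), and the next ratio of observed to even spread, on chromosome 15, was 1.74 against 3.43 for chromosome 9. In gene order, the stretch from Gramd1b to Plet1os held 7 such genes among 65 measured, that from Ppp2r3a to Usp4 6 among 64, and that from Klhdc8b to Cmtm7 0 among 64. Nxpe4 and Nnmt are near neighbours, at places 187 and 191 of the 647 measured genes. The reticulocalbin gene Rcn2, published as a candidate for Ath29, read 652 and 844 in Ath29 mice against 1381 and 1127 in B6 mice, a log2 difference of -1.13 on chow and -0.41 on Western diet. Its other probe set gave -0.79 and -0.97. Rcn2, at place 237, lies in the stretch from Plet1 to Clk3. That stretch held 1 gene shared at 1.5-fold, Sln of the heart muscle list, among 65 measured.

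**Figure D2:**
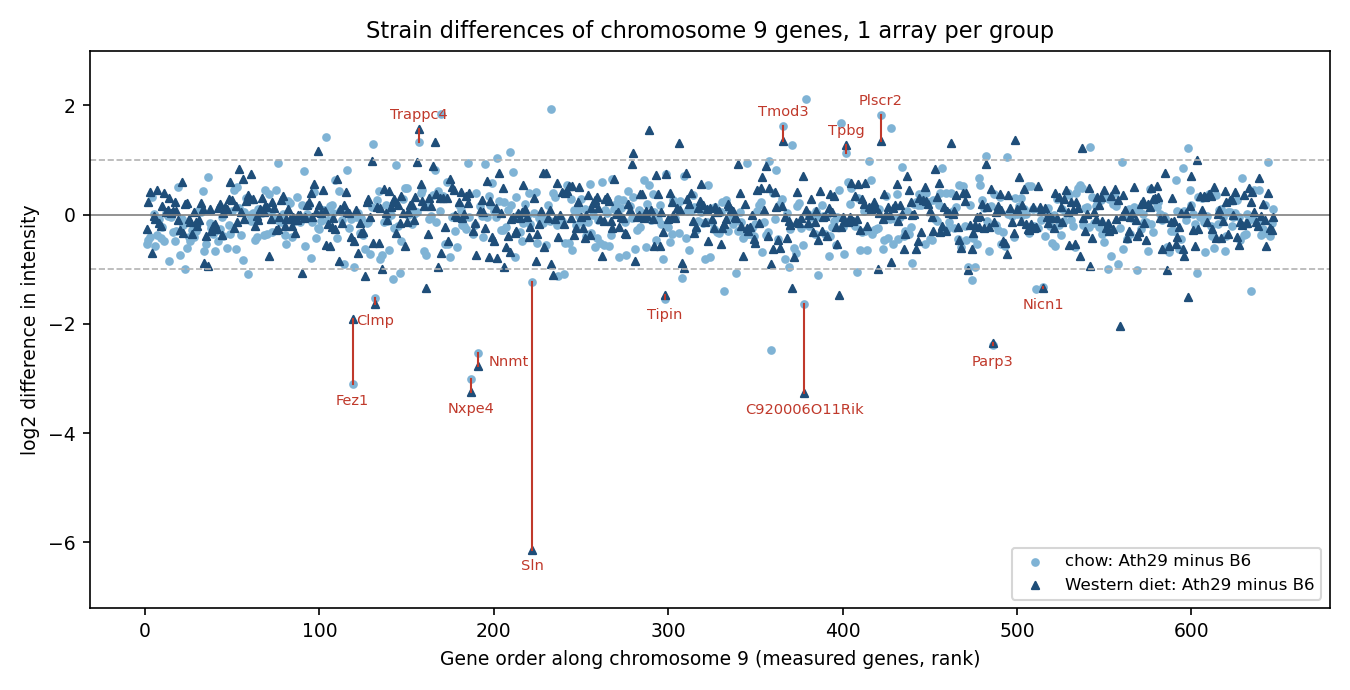
Log2 difference in intensity between Ath29 and B6 mice on chow (circles) and Western diet (triangles) for the 647 measured genes of chromosome 9, in gene order, with dashed lines at 2-fold. Red lines join both values of the 13 genes at least 2-fold different in the same direction on both diets, of which 9 lie below and 4 above.

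The cholesterol synthesis list had a median log2 difference between Ath29 and B6 mice of -0.35 over 17 genes on chow and -0.22 on Western diet, at the 0.65 and 1.32 percentiles of 10000 random lists matched on expression. On each diet 12 of the 17 genes were below 0 and 5 above, and 2 on chow and 1 on Western diet were at least 2-fold lower. Msmo1, a sterol oxidase, was -1.65 and -0.62, Sc5d, a sterol desaturase gene of chromosome 9, -0.74 and -1.01 with another probe set at 0.01 and -0.21, and Srebf2, the regulator of the pathway, -0.35 and -0.37. Fdft1 (0.77 and -0.63) and the squalene epoxidase Sqle (-0.95 and 0.33) went in opposite directions. With quantile normalization, with no filter or a stricter one on low values, or with probe sets that can bind several transcripts left out, the list no longer lay under the 2.5 percentile on both diets. The actin 3' to middle ratio and the bioB control were also higher in both Ath29 arrays than in both B6 arrays, while the Gapdh 3' to 5' ratio was lower.

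On chow 253 genes were at least 2-fold higher and 229 lower in Ath29 than in B6 mice, 52.5% higher. With arrays set to a common 75th percentile the split was 310 higher and 170 lower, and without probe sets that can bind several transcripts 195 higher and 243 lower. The plasma cell gene Jchain was higher by at least 4.01 log2 units, and A530053G22Rik and Trim67 by at least 2.98 and 2.88, with B6 chow at the floor. Brown fat genes were higher with a median of 1.06 over 13 genes, led by Elovl3 at 2.29 and Otop1 at 1.67. White fat genes had a median of 0.58, with Aqp7 at 2.09, and fatty acid oxidation genes 0.66, with Ucp3 at 2.01 and Ehhadh at 1.65. Oxidative phosphorylation genes had a median of 0.43, fatty acid synthesis genes 0.47 and genes of cholesterol efflux 0.27. On this array pair, fat signal was lowest in B6 chow. All 20 contractile smooth muscle genes were lower in Ath29 mice on chow, with a median of -0.23, and Tpm1 (-1.40), Mustn1 (-1.36), Myh11 (-1.30) and Myl9 (-1.25) by over 2-fold. Ribosomal protein genes had a median of -0.23 as well, at the 0.365 percentile. The actin 3' to middle ratio was highest in Ath29 chow, where both Gapdh ratios were lowest. All 20 immediate-early genes were also lower, with a median of -0.47, Fos at -3.01, Klf2 at -1.93 and Ccn1 at -1.66, and with the stricter filter this list lay under the 2.5 percentile on both diets. The clock genes Nr1d1 and Dbp were -1.43 and -0.97 and Ciart 1.12, with a list median of -0.29.

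On Western diet 99 genes were at least 2-fold higher and 238 lower in Ath29 than in B6 mice. The lowest were the muscle genes Myl7, the atrial myosin light chain (-7.73, a bound), Mb, the oxygen-storing myoglobin (-7.24) and Myh6, the adult cardiac myosin heavy chain (-6.45). The list of 15 heart muscle genes had a median of -3.72, and 12 of them were at least 2-fold lower. Skeletal muscle genes had a median of -1.14. The fat, lipid and mitochondrial lists that were higher on chow were lower here: brown fat -0.95, with Elovl3 at -2.24, white fat -0.65, fatty acid oxidation -0.65, oxidative phosphorylation -0.47, fatty acid synthesis -0.49 and cholesterol efflux -0.31. The fat and heart muscle signal was highest in B6 Western, one side of this difference. Interferon response genes had a median of -0.37, below the 2.5 percentile, against 0.01 on chow. Their median diet difference was 0.25 in B6 mice, at the 99.3 percentile, and 0.03 in Ath29 mice. Matrix and fibroblast genes had a median of 0.14, with Col1a1 at 0.52, against -0.16 on chow. Plekha7 was the highest single value at 6.09 or more, from a probe set that read 655 in Ath29 Western and 18.7 or less in the others, and 2 other Plekha7 probe sets showed no such signal. Il6 followed Ttll10 (3.38) with 2.83.

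The comparison of diets asks which aortic transcripts differ after 2 weeks of Western diet in each strain. Of the neutrophil-attracting chemokines, Cxcl1 was higher on Western diet by 3.78-fold in B6 and 4.66-fold in Ath29 mice. Cxcl2 went from 11.3 to 67.5 intensity units in B6 and from 17.8 to 176 in Ath29 mice, with both chow values in the range of background. The neutrophil marker list had median diet differences of 0.04 in B6 and -0.17 in Ath29 mice. The monocyte chemokine Ccl8 was 4.22-fold and 3.06-fold higher. The acute phase gene Ptx3, a pentraxin, was 24.6-fold and 4.04-fold higher. Fgl1, a fibrinogen-like secreted protein, read 377 on Western diet against 13.2 on chow, a background value, in B6 mice, and 389 against 68.9 in Ath29 mice. Il6 was higher by at least 1.69 log2 units in B6 and 4.52 in Ath29 mice, since both chow arrays lay at the floor. In B6 and Ath29 mice, log2 differences were 2.17 and 2.56 for Chil3, a chitinase-like protein of macrophages, 1.63 and 1.68 for Ch25h, the cholesterol hydroxylase, 1.78 and 1.83 for the myeloid receptor Cd300lb, 2.37 and 1.52 for Wfdc21, 1.80 and 1.39 for Mup5, and 1.38 and 1.65 for Serpina3n. The chow values of Chil3, Cd300lb and Serpina3n lay below 27.4 in both strains.

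Macrophage genes had a median of 0.87 in B6 and 0.69 in Ath29 mice, and all 18 were above 0 in each strain. Mpeg1, a pore-forming protein (2.14 and 1.33), the protease Ctss (1.43 and 1.24), Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages (1.23 and 2.32), and Cd68 (0.87 and 0.84) are examples. The 15 measured chemokine and cytokine genes had medians of 0.60 and 0.57, with 7 in B6 and 6 in Ath29 mice at least 2-fold higher and 0 at least 2-fold lower. Of the 30 listed, 12 lay below the filter and 3 had no probe set of their own. Among those below the filter was the monocyte chemokine Ccl2, at the floor on every array. Antigen presentation genes of MHC class II had medians of 0.86 and 0.30, with H2-Ab1 at 1.86 and 0.84. All 3 lists lay in the top 2.5% of random lists in each strain. Between strains, the median difference of macrophage genes was 0.19 on chow and 0.00 on Western diet, that of chemokines 0.17 and 0.21, and that of antigen presentation genes 0.49 and -0.10. The macrophage and antigen presentation values on chow lay in the top 2.5% of random lists. The fat lists, higher in B6 mice on Western diet, were lower in Ath29 mice (brown fat 1.57 and -0.38). The antigen presentation list left that range with no filter on low values, with the stricter filter, and without probe sets that can bind several transcripts.

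At least 2-fold in the same direction in both strains, 29 genes were higher on Western diet and 1 lower, against 35 in opposite directions. Independent differences would give 6.42 higher and 1.17 lower. The 29 higher genes exceed that, while the 1 lower gene does not. Together they do not outnumber the 35 in opposite directions. The lower gene was Igha, the heavy chain of immunoglobulin A, with -1.27 in B6 and -1.24 in Ath29 mice. Among the higher were the sterol exporter Abcg1 (2.08 and 1.06), the monocyte chemokine receptor Ccr2 (1.67 and 1.10), the fungal pattern receptor Clec7a (1.98 and 1.20), Saa3, a serum amyloid (3.01 and 1.32), and the haemoglobin scavenger Hp (2.14 and 1.02). Below 2-fold in at least 1 strain, lower values in both were found for C1qtnf6 (-1.37 and -0.99), Ppbp (-0.99 and -1.20), Casq1 (-1.51 and -0.74), Cckbr (-1.12 and -0.89), Aoc1 (-0.93 and -2.01), Zfp772 (-0.98 and -0.95), Igsf9 (-0.76 and -0.87), Krtap21-1 (-0.85 and -1.26), Fam227a (-0.79 and -1.55), Gm7694 (-0.77 and -0.77) and Vmac (-0.76 and -0.74). The limma additive fit called 0 genes for diet, with 291 at an unadjusted p under 0.05 and a lowest adjusted p of 0.499.

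**Figure D3:**
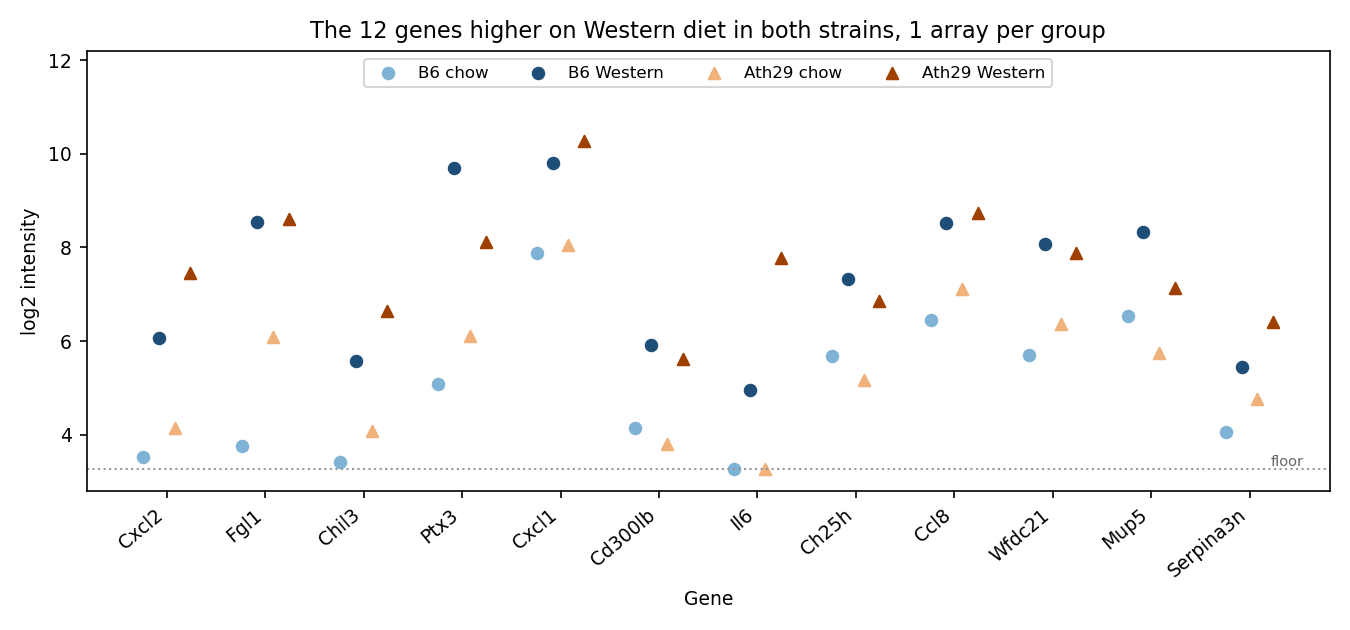
Log2 intensity in each of the 4 arrays for the 12 genes with the largest difference on Western diet shared by both strains (circles B6, triangles Ath29, darker for Western diet). Both Western diet values lie above both chow values for each of the 12 genes, and Il6 lies at the floor (dotted line) on chow.

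In B6 mice alone, 482 genes were at least 2-fold higher on Western diet and 137 lower. Heart muscle genes were higher, with a median of 3.21 over 15 genes, Myl7 at 5.28 and Sln at 4.72, but Myl2 was 0.23 and Myh7 -0.25. Skeletal muscle genes had a median of 0.73, with Mb at 4.74. Brown fat genes had a median of 1.57, with Elovl3 at 3.02, white fat genes 0.77, with Aqp7 at 2.69, and fatty acid oxidation genes 0.91, with Ucp3 at 2.43 and Fabp3 at 2.25. All 24 oxidative phosphorylation genes were higher, with a median of 0.58. Fatty acid synthesis genes had a median of 0.78, with Elovl6 at 1.51, and cholesterol efflux genes 0.66, with Scarb1 at 1.19. Matrix and fibroblast genes had a median of -0.34, with Col1a1 at -0.96, and contractile smooth muscle genes -0.28. The lowest single genes were Nap1l3 (-3.01, a bound), 2900055J20Rik (-2.29) and Hhip, an inhibitor of hedgehog signalling (-2.22).

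In Ath29 mice, 156 genes were at least 2-fold higher on Western diet and 100 lower. Of the lists that were higher in B6 mice, brown fat had a median of -0.38, white fat -0.29, fatty acid oxidation -0.36, oxidative phosphorylation -0.24, heart muscle -0.12, skeletal muscle 0.04, fatty acid synthesis -0.09 and cholesterol efflux 0.05. Immediate-early genes had a median of 0.35 with 19 of 20 above 0, against -0.03 in B6 mice. Contractile smooth muscle genes had a median of 0.09, also with 19 of 20 above 0. The actin 3' to middle ratio of these arrays was 10.2 on chow and 7.62 on Western diet. Adhesion genes of leukocytes and endothelium had a median of 0.32, in the top 2.5% of random lists, with Icam1 at 0.69, against -0.19 in B6 mice. The 6 measured B and plasma cell genes had a median of -0.89, with Jchain at -2.26 and Ms4a1 at -1.23, against -0.24 in B6 mice. Il1rn, the interleukin receptor antagonist, was 2.02, Mmp3, a matrix protease, 1.67 and its inhibitor Timp1 1.57. Hand2, a transcription factor of the developing heart, was the lowest at -3.22.

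Diet differences went in opposite directions in the 2 strains by at least 2-fold for 35 genes, 29 of them higher in B6 and lower in Ath29 mice. The most negative differences between the diet differences were those of muscle genes: Myl7 -8.25, Myh6 -6.25, Mb -6.23, the sarcomere protein Myom2 -5.17, Sln -4.91 and Actc1 -4.79. The most positive were Plekha7 at 7.08, 2900055J20Rik at 4.19, the calcium-dependent kinase Camk4 at 3.54, Wnt3a at 2.99, and Il6 and the tight junction gene Ocln at 2.83 each. The values of Myl7, Plekha7 and Il6 each rest on at least 1 array at the floor. Those of Mb, Myom2, 2900055J20Rik, Wnt3a and Ocln rest on at least 1 array below 27.4 and are not exact either. With the floor lowered to 1, another Plekha7 probe set is used and the difference is -0.93.

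**Figure D4:**
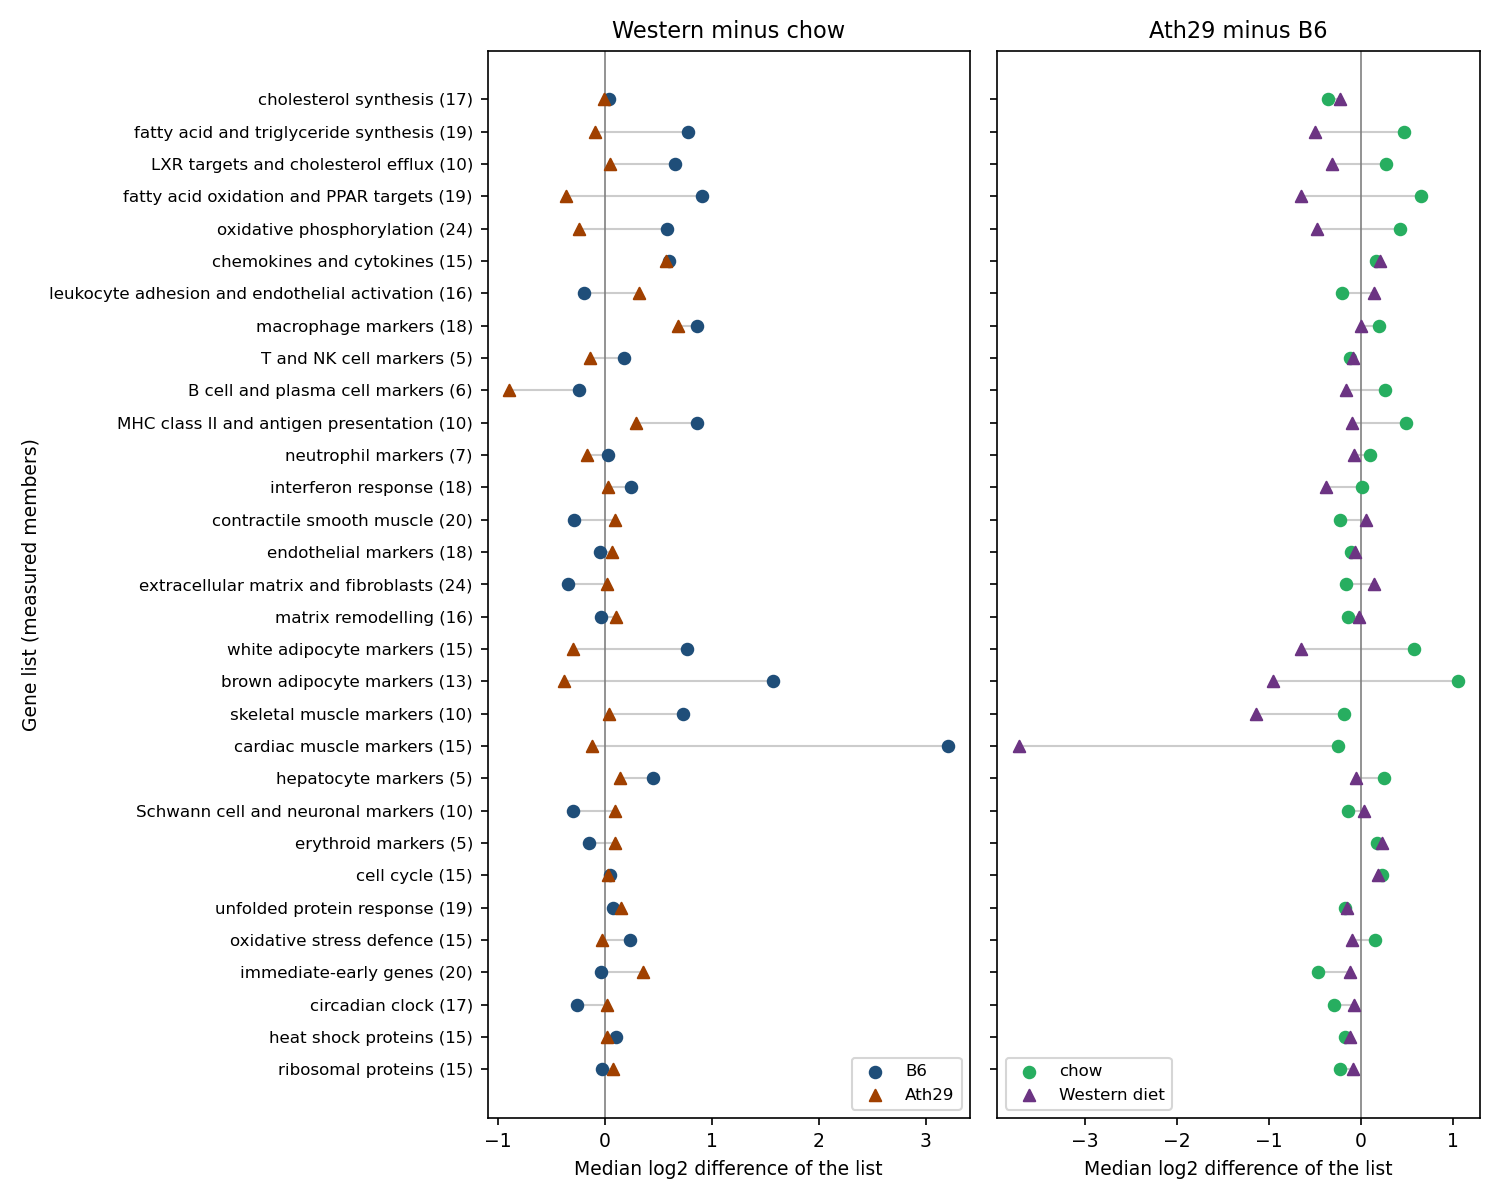
Median log2 difference of each of the 31 gene lists between diets (left, B6 circles, Ath29 triangles) and between strains (right, chow circles, Western diet triangles), with the number of measured members in brackets. Macrophage, chemokine and MHC class II lists are above 0 for diet in both strains, while brown fat is 1.57 in B6 and -0.38 in Ath29 mice.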

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

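The tests of explanations in this part were chosen after the results were seen, while the counts, shares and lists they start from were fixed before. The diet differences of the 2 strains stand apart for 35 genes, which differed by at least 2-fold in opposite directions. They were singled out because the arrays of B6 mice moved one way and those of Ath29 mice the other, and the difference between strains was not tested, since each group has 1 array. Among the named genes whose diet differences had opposite signs, the diet difference in Ath29 minus that in B6 mice was Myl7 -8.25, Myh6 -6.25, Mb -6.23, Myom2 -5.17, Sln -4.91 and Actc1 -4.79 on one side, and Plekha7 7.08 (-0.93 with another probe set), 2900055J20Rik 4.19, Camk4 3.54, Wnt3a 2.99 and Ocln 2.83 on the other. Of these genes, Myl7, Mb, Myom2, Plekha7, 2900055J20Rik, Wnt3a and Ocln had a value below 27.4 on at least 1 array, so their differences are not exact. The lists in the top 2.5% of random lists in B6 mice and the bottom 2.5% in Ath29 mice were fatty acid oxidation (0.91 and -0.36), oxidative phosphorylation (0.58 and -0.24), white fat (0.77 and -0.29) and brown fat (1.57 and -0.38).

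Fat and heart muscle transcripts were high in the B6 Western array. A response to Western diet common to both strains is argued against for brown fat genes, whose median diet difference was -0.38 in Ath29 mice. That 85.7% of the measured heart muscle and brown fat genes were highest in B6 Western describes the pattern and does not separate heart or vein muscle and fat left on that aorta from a diet response limited to B6 mice. At least 2-fold above every other array there were 12 of 15 heart muscle genes, but 1 of 13 brown fat and 0 of 15 white fat genes. Both explanations stay open, because strain, diet and dissection coincide in 1 array.

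The strain differences shared by both diets were concentrated on chromosome 9. Chance spread over the chromosomes is argued against, since no random set of 30 genes held over 7 chromosome 9 genes. Carried-over tissue or RNA quality has no reason to pick a chromosome, and the 43.3% share (18.1% with no filter on low values) lies above the 5.52% of all genes, with an interval from 27.4 to 60.8. Donor sequence variants under single probe sets stay open: of the 21 lower and 7 higher chromosome 9 genes at 1.5-fold, 6 and 3 had other probe sets, and 37.5% of 8 (interval 13.7 to 69.4) and 14.3% of 7 (2.57 to 51.3) went the same way on both diets, against 42.9% for strain genes of other chromosomes in either direction, 60.7% (42.4 to 76.4) for genes higher on Western diet and 30% for those lower. These intervals overlap, so probe variants and true expression differences of the congenic segment, the biological explanation in the design, cannot be told apart for these genes. The labels do not give the limits of the donor segment, so which chromosome 9 genes lie inside it is not known here. Strain genes of other chromosomes are a weak reference. Over all chromosomes at 1.5-fold, independent differences would put 47.5 genes higher and 89.4 lower, against 51 and 97 found.

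The measured macrophage and chemokine lists were higher on Western diet in both strains. More fat on the Western diet aortas is argued against as the common cause, since the brown fat list was -0.38 in Ath29 mice. Stress of handling stays open: the immediate-early list was -0.0314 in B6 mice and 0.35 in Ath29 mice, which neither shows it nor excludes it. A response of the vessel wall to Western diet remains a hypothesis.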

How the results depend on the processing

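The tests here were fixed before the data were examined, except leaving out muscle and fat list genes and leaving out the B6 Western array with its simulations. Over 118 quantities, 971 of 975 values under the alternatives kept their sign, 888 staying within 1 SD of the reported value and 83 moving further. The quantities are gene differences, list medians and the count of genes in opposite directions on the 2 diets. For a gene the SD is that of its 2 strain differences (at least 0.01 log2 units), and for a list that of random list medians. For the count a factor of 1.5 was allowed. The other 4 reversed: without probe sets that can bind several transcripts, the mean strain difference was -0.80 for Tmod3 and -0.29 for Trappc4, and with no floor beyond 1 a different Plekha7 probe set is read, giving -0.45 for strain on Western diet and -0.93 for strain by diet. The number within 1 SD says little for strain by diet values, whose SD is a large fixed share of the value itself. Both filter alternatives leave the value of a kept gene unchanged, and genes lost under an alternative were not counted. With no filter on low values, where more genes are counted, genes at least 2-fold different numbered 959 and 826 for strain on chow and Western diet, 1075 and 733 for diet in B6 and Ath29 mice, 72 and 68 shared for strain and diet, and 71 for strain by diet, with 18.1% of shared strain genes on chromosome 9 and 2 shifted lists. With the filter at the 75th percentile, which counts fewer genes, these were 180, 126, 297, 57, 12, 16 and 11, and the immediate-early list was lower in Ath29 mice on both diets. At 1.5-fold they were 1981, 1581, 2002, 1217, 148, 142 and 268, with 18.9% on chromosome 9, and at 3-fold 79, 67, 168, 47, 7, 9 and 6, with 71.4%. Without probe sets that can bind several transcripts 2 lists were shifted against 4, and the cause was not tested. The limma fit called 0 genes for strain and 0 for diet, with 304 and 291 at an unadjusted p under 0.05, although it called 18 of 50 simulated 2-fold and 50 of 50 simulated 4-fold strain differences. Those simulated rates need not hold for the real arrays, since simulated genes of similar level had the same spread. Of the unchanged simulated genes 2 differed in opposite directions, against 73 genes in the real arrays. Without the B6 Western array 111 strain genes were shared, 17.1% on chromosome 9. Both differences then use the B6 chow array, and 100 simulations of unchanged groups sharing it gave 112 to 188 genes, with at most 9.52% on chromosome 9. The simulated spread came from strain by diet differences, which include the B6 Western array, and 111 lies below every simulation. The count therefore cannot tell whether strain differences are shared. Under quantile normalization 27 of the 30 shared strain genes and 27 of the 30 shared diet genes remained, and with the mean of all probe sets 22 and 29. Macrophage and chemokine lists stayed shifted for diet under each scaling, filter, floor and probe set alternative. The cholesterol synthesis list was lost under quantile normalization, with no filter, with the stricter filter and without probe sets that can bind several transcripts, and the antigen presentation list under the last 3 of these. Further lists passed the percentile limits in opposite directions for diet under some alternatives. Without probe sets that can bind several transcripts these were contractile smooth muscle, fatty acid synthesis and skeletal muscle. Contractile smooth muscle also did so under quantile normalization and with the mean of all probe sets, and fatty acid synthesis with the stricter filter. Leaving out muscle and fat list genes left 24 shared strain genes, 50% of them on chromosome 9. No array can be left out in turn within a group, and no paired analysis was possible because nothing pairs mice across groups, although the limma fit compares strains within diets and diets within strains. The floor limits low genes, and by its definition about 25% of values on each array lie at it.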

Other observations

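The genes of this part were chosen after their values were seen, except members of the lists. The mast cell gene Tpsab1 was higher in Ath29 mice by 2.42 on chow and 2.31 on Western diet, with B6 values in the range of background, while the chymase Cma1 gave 0.68 and -0.42, the carboxypeptidase Cpa3 0.81 and -1.18, and the tryptase Tpsb2 0.57 and -0.02. Of the platelet genes, Ppbp and Tubb1 were at least 2-fold lower in Ath29 mice on both diets, while the platelet chemokine Pf4 differed by -0.14 and -0.23, Gp1bb by -0.06 and 0.32 and Clec1b by -0.18 and -0.89. Myh1, a myosin of fast skeletal muscle, read 176 and 373 in B6 mice and 6.21 and 5.89 in Ath29 mice. Of the 10 measured skeletal muscle genes, 7 were below 0 on chow and 8 on Western diet, 2 and 5 of them by at least 2-fold.

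Endothelial genes had median strain differences of -0.10 on chow and -0.06 on Western diet and median diet differences of -0.04 in B6 and 0.06 in Ath29 mice, although Gpihbp1, the lipase anchor of capillaries, was 1.29 and -1.25 between strains. In the same order, T and NK cell genes had medians of -0.12, -0.09, 0.18 and -0.14, and neutrophil genes 0.10, -0.07, 0.04 and -0.17. The neutrophil gene S100a8 differed between diets by 0.11 in B6 and 0.32 in Ath29 mice. Nerve genes had medians of -0.14, 0.04, -0.29 and 0.10, and red cell genes 0.17, 0.24, -0.15 and 0.10. Cell cycle genes had medians of 0.23, 0.18, 0.05 and 0.03, unfolded protein response genes -0.17, -0.15, 0.08 and 0.16, oxidative stress genes 0.15, -0.10, 0.24 and -0.02, heat shock genes -0.17, -0.12, 0.10 and 0.02, and matrix remodelling genes -0.13, -0.02, -0.03 and 0.10. Ribosomal protein genes, abundant and meant as a steady reference, had medians of -0.23, -0.09, -0.02 and 0.08, and the strain value on chow lay at the 0.365 percentile. Other percentiles in the outer 2.5% on either side were 99.2 for oxidative stress and 98.5 for cell cycle between strains on chow, and 99.4 for oxidative stress and 1.90 for nerve between diets in B6 mice.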
